A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

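Expression was measured on 21 Affymetrix arrays from 7 groups of 3 replicates, with group and replicate number taken from the sample titles. RMA is named per the submitters' processing notes, with no version. GeneSpring 11.5.1 is named in the header of the authors' fold change table. The deposited value table holds log2 values for 10928 probe sets. The base was read from the values, since differences of group means in CSM match the logarithm of the deposited fold changes to within 0.001 for 100% of probe sets. In YPD only 2.80% (gal11-myc med3Δ) and 2.74% (gal11Δ med3Δ) matched, with correlations of 0.992 and 0.996, so the deposited YPD fold changes are close to these values but not taken from them exactly. Each probe set in the deposited table is centred on its median, which is exactly 0 for 100% of probe sets over the 9 YPD arrays of wild type and mutants, over the 9 CSM arrays, and over the 3 BY4742 arrays. Absolute levels and any difference between these 3 sets are therefore lost, so BY4742 against wild type, gal11Δ med3Δ against BY4742, and wild type in CSM against YPD could not be computed. The deposited fold change table gives signed linear fold changes, not log2 per the file headers, for 5 comparisons. The same table gives a p-value and a corrected p-value per probe set, and the authors state neither the test nor the correction. Per the file headers, probe sets were filtered differently for the YPD and CSM comparisons in that table.

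Gene symbols came from the table that pairs the probe sets with genes. Of the 10928 probe sets, 7244 had 1 symbol, 1 had several and 3683 had none. Of the 7244, 5498 matched the S. cerevisiae gene table (assembly R64, used for names only) and 1746 did not. After averaging the 47 genes with more than 1 probe set, 5449 genes were tested. The plan was to keep the probe set with the highest mean, but centring leaves no level to rank by, so the mean of a gene's probe sets was used. For the same reason a filter on dim probe sets, a variance trend with level and a second quantile normalization could not be run. Symbols were brought up to date for 12 probe sets.

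All 21 arrays were fitted in 1 model of 7 group means with limma (lmFit and eBayes, 14 residual degrees of freedom), so that all groups share an estimate of the spread. BY4742 adds only to that estimate. Each mutant was compared with the wild type in each medium, with the other mutant in each medium, and as an interaction between media. p-values were 2-sided and adjusted by Benjamini-Hochberg over the 5449 genes. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. A gene's groups are said not to overlap when all 3 arrays of a group lie above all 3 of the other. The chance share given beside such counts holds per gene for arrays that are free to exchange. Genes can share shifts of whole arrays, so a larger share does not by itself show an effect of the strain.

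The comparisons, the tests, 30 gene lists and the rule for naming genes were written before the data were examined. The rule names the targeted genes and strain markers, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (5 and 5 in comparisons between mutants and in interactions, with the mating type lists), and up to 4 members of each list with the largest absolute difference. Genes that share a probe set are not named. The lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a comparison, and again with a correlation estimated per list. Members counted as rising or falling had an adjusted p under 0.05 at any size. The fry test, which asks whether a list's genes move 1 way on balance without comparing them with other genes, was run beside it. Tests of the lists between the mutants and in the interactions were added after the data were seen. A test of TATA boxes was planned but not run, because no genome came with the series.

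Overlap between mutants was counted for genes called in the same direction, beside the count from independent calls. The correlation and covariance of 2 comparisons across genes were set beside their means in 100 simulated data sets of independent arrays with no effect and the same shared controls. In simulated data for gal11Δ med3Δ against wild type in YPD, 100% of changes of 1.5 and 91% of changes of 0.75 (log2) among 5449 genes were recovered at an adjusted p under 0.05, and 5.91% of calls were false. In CSM these were 99%, 91% and 4.52%. For gal11-myc med3Δ they were 98%, 86% and 3.66% in YPD, and 100%, 92% and 4.95% in CSM. Between the mutants they were 98%, 92% and 2.56% in YPD, and 97%, 85% and 5.70% in CSM. For the interactions they were 97%, 74% and 4.47% in gal11Δ med3Δ, and 99%, 63% and 4.71% in gal11-myc med3Δ. Each simulated set had 200 changed genes. Its noise was normal and independent between arrays, with 1 spread per gene in all groups. The real groups had unequal spread (median gene SD 0.046 in gal11-myc med3Δ to 0.141 in gal11Δ med3Δ, both in CSM). The simulated shares of false calls are therefore not error rates of the real calls. A general stress list shifted by -0.5 was recovered, with 0 of the other lists called. Simulated genes were also independent of each other, so that 0 does not show how the list test behaves where genes move together.

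Whether replicate numbers pair the arrays was checked by correlating deviations from the group means across genes. In YPD all 9 pairs of same-numbered arrays had a correlation above 0.1 (0.146 to 0.606), and in CSM 2 of 9 did (-0.215 to 0.221). In 7 YPD pairs the own number gave the highest value, but not for replicate 1 of the wild type with either mutant. Deviations from a mean of 3 arrays are not independent, so a shift shared by the arrays numbered 3 would raise the other values too. Numbers thus pair at least some of the YPD arrays. The block of replicate number was therefore run as an alternative, over all arrays and within each medium. Further alternatives were leaving out each array, centring each array on the median of its genes, array weights with a robust variance, a fit of only the groups compared, a 1.5-fold threshold, and the deposited fold changes. Leaving out BY4742, the 3 YPD arrays numbered 3 or the probe sets that can match several genes was added after the data were seen, as were the block within each medium, the combination of array weights without BY4742, and the alternatives for the overlap other than a 1.5-fold threshold and pairs across media. A list of meiosis genes was also added after some members had been seen. Its p-values were adjusted over 8 tests, 4 of which belong to a result that is left out here. Other splits of the arrays into groups of the same sizes were counted for every comparison, with 100 drawn from the 200 possible splits of the medium labels for an interaction. After the data were seen, the real split was also set beside those that part as many pairs of same-numbered YPD arrays.

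R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.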

Results

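Transcript levels of budding yeast were measured on 21 arrays with biotin-labelled RNA from mid-log cultures grown at 30 °C. The arrays form 7 groups of 3 replicates. The wild type labelled MATa, which the authors' deposited table calls BY4741, was grown in rich medium (YPD) and in complete synthetic medium (CSM). So were 2 mutants of the Mediator tail, the part of the RNA polymerase II coactivator that activators contact. The first mutant, gal11Δ med3Δ, is labelled MATα and lacks Gal11 (also called Med15) and Med3. The second, gal11-myc med3Δ, is labelled MATa, lacks Med3 (gene PGD1) and carries a myc-tagged Gal11. A further wild type, BY4742, was grown in YPD only. The number of arrays limits the precision, and the labels do not say that the replicates came from separate cultures. A p-value therefore sets a difference against the spread between these arrays, pooled over all 7 groups, and may not cover the spread between cultures. That spread was unequal, with a median gene SD from 0.046 in gal11-myc med3Δ to 0.141 in gal11Δ med3Δ, both in CSM. Values below are log2 differences between group means ± SE, with n = 3 arrays per group, and "called" means an adjusted p under 0.05 and a difference of at least 2-fold.

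The targeted genes and strain markers show which strain each group holds. GAL11 fell in gal11Δ med3Δ, by -6.43 ± 0.15 in YPD and -5.62 ± 0.15 in CSM. In gal11-myc med3Δ its differences were -0.59 ± 0.15 and -0.55 ± 0.15. PGD1, the gene for Med3, fell in gal11Δ med3Δ (-4.51 ± 0.14 in YPD, -4.26 ± 0.14 in CSM) and in gal11-myc med3Δ (-4.30 ± 0.14 and -4.05 ± 0.14). URA3, the marker that replaced PGD1 in gal11-myc med3Δ, rose there by 7.46 ± 0.18 in YPD and 6.52 ± 0.18 in CSM. LEU2, carried on that strain's plasmid, rose by 3.35 ± 0.49 and 4.69 ± 0.49. LYS2, a lysine biosynthesis gene, fell by -6.50 ± 0.13 and -6.88 ± 0.13 in gal11Δ med3Δ, whose label lists no lysine marker, and by -0.92 ± 0.13 in gal11-myc med3Δ in CSM. In gal11-myc med3Δ the CSM effect minus the YPD effect was -1.18 for LYS2. MET17, deleted in the MATa wild type under the name met15, differed by 0.17 or less in size in all 4 comparisons, although the gal11-myc med3Δ label does not list that deletion. A fission yeast his5 probe set was checked because that gene is part of the HIS3MX cassette, and it was not called (-0.03 ± 0.07 in gal11-myc med3Δ in YPD, adjusted p = 0.836). SRB4, the last gene of this list, was not measured.

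**Figure D1:**
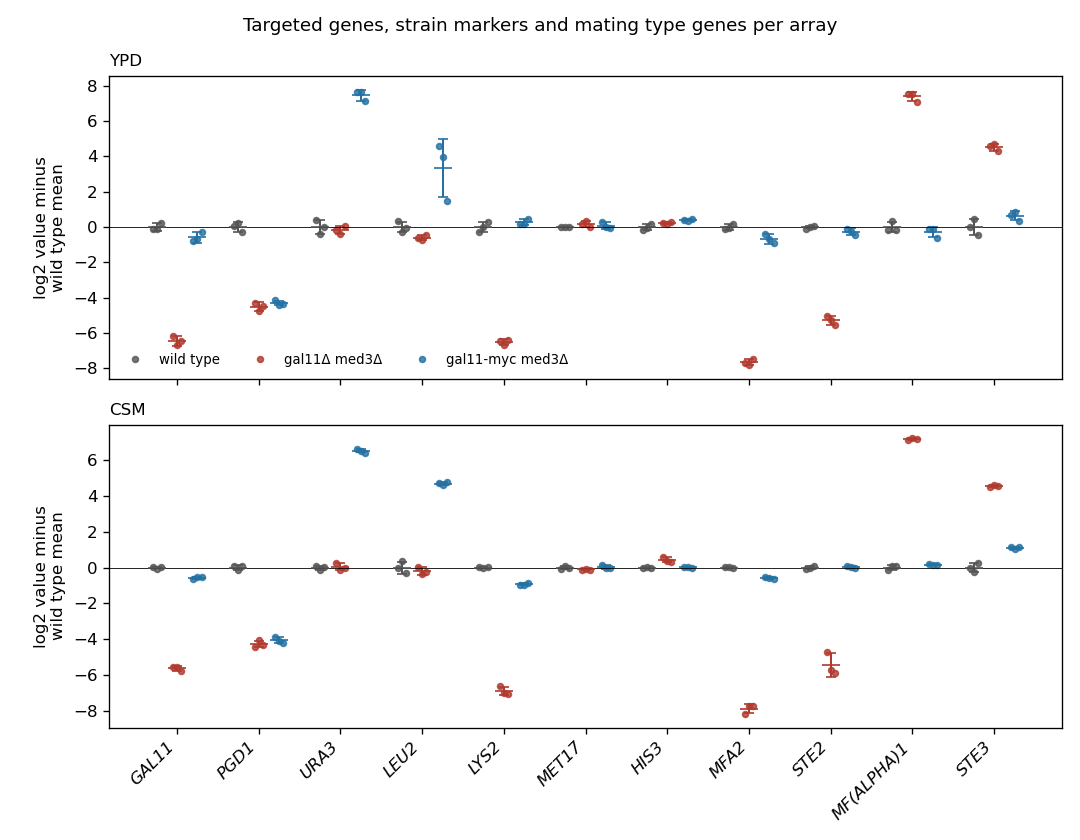
Log2 values of the targeted genes, the strain markers and 4 mating type genes on each array, minus the mean of the 3 wild type arrays in the same medium (y axis, log2). Points are arrays, dashes are means of 3 arrays and bars are SD. GAL11 and LYS2 lie low on the gal11Δ med3Δ arrays, PGD1 lies low in both mutants, and URA3 lies high on the gal11-myc med3Δ arrays.

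Loss of Gal11 and Med3 in YPD was compared with the MATa wild type to ask which genes depend on the tail in rich medium. The largest differences were in genes that mark mating type. All 7 a-specific genes fell, among them MFA2 (-7.65 ± 0.13), an a-factor gene, and STE2 (-5.28 ± 0.21), the α-factor receptor gene. All 5 α-specific genes rose, among them MF(ALPHA)1 (7.39 ± 0.15) and STE3 (4.51 ± 0.19), the a-factor receptor gene. Outside these lists, the mating type genes HMLALPHA1 rose (8.20 ± 0.15) and HMRA1 fell (-7.19 ± 0.18). Apart from these, the targeted genes and the strain markers, the largest falls were in YRO2 (-5.18 ± 0.31), HSP30 (-4.98 ± 0.29), a plasma membrane heat shock protein, and CHA1 (-4.58 ± 0.31), which breaks down serine and threonine. Large rises were in POX1 (3.57 ± 0.25), the peroxisomal fatty acid oxidase, CDA1 (3.37 ± 0.19), a spore wall chitin deacetylase, COS12 (3.35 ± 0.29), a subtelomeric gene, and ADH2 (3.18 ± 0.36), the glucose-repressed alcohol dehydrogenase. MIG3 (3.02 ± 0.36) and MHT1 (2.92 ± 0.38) also rose.

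Of 24 sulfur amino acid genes in gal11Δ med3Δ in YPD, 19 rose, 0 fell and 5 did not pass the test (21 rose when adjusted over the list alone), with MUP3 (2.71 ± 0.40), a methionine permease, and MET2 (2.30 ± 0.37) among the largest. The list lay above other genes by camera (adjusted p = 2.98e-05, and adjusted p = 0.437 with an estimated correlation). Of 25 genes under nitrogen catabolite repression, 19 rose, 2 fell and 4 did not pass (19 and 2 adjusted over the list alone), led by the amino acid permease gene GAP1 (2.65 ± 0.18) and by GDH2 (1.87 ± 0.23). Their camera adjusted p was 6.18e-05, and the adjusted p = 0.291 with an estimated correlation. Of 30 glucose-repressed and gluconeogenic genes, 16 rose and 6 fell (16 and 6 adjusted over the list alone). The fatty acid oxidation gene SPS19 rose (2.42 ± 0.14) and the gluconeogenic phosphatase gene FBP1 fell (-4.41 ± 0.76). That list had a camera adjusted p = 0.0313 and an adjusted p = 0.502 with an estimated correlation. It lost its call without wild type YPD replicate 3 (adjusted p = 0.0782), without gal11Δ med3Δ YPD replicate 3 (0.0516) and without the 3 YPD arrays numbered 3 (0.130).

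Of 35 cell wall genes in gal11Δ med3Δ in YPD, 19 fell and 5 rose (19 and 5 adjusted over the list alone), including DSE2 (-2.07 ± 0.16), SCW11 (-2.06 ± 0.20) and the mannoprotein gene CWP1 (-1.99 ± 0.19). Their camera adjusted p was 0.000252, and the adjusted p = 0.291 with an estimated correlation. Of 30 heat shock and chaperone genes, 19 rose and 4 fell (21 and 4 adjusted over the list alone). The mitochondrial chaperone gene HSP78 rose (1.58 ± 0.39), while HSP30, HSP12 (-3.68 ± 0.69) and HSP26 (-1.80 ± 0.38) fell. As a whole the list had a camera adjusted p = 0.00195 and an adjusted p = 0.502 with an estimated correlation. Of 36 general stress genes of Msn2 and Msn4, 12 fell and 5 rose (12 and 5 adjusted over the list alone), with YGP1 (-4.09 ± 0.39) lowest (camera adjusted p = 0.0343, and adjusted p = 0.723 with an estimated correlation). That list lost its call without wild type YPD replicate 1 (adjusted p = 0.0831) or 3 (0.0782), without gal11Δ med3Δ YPD replicate 2 (0.0508) and without the 3 YPD arrays numbered 3 (0.0596). Of 50 ribosome biogenesis genes, 36 fell and 2 rose (38 and 2 adjusted over the list alone), all by less than 2-fold, with NOG1 at -0.63 ± 0.14 (camera adjusted p = 8.70e-08, and adjusted p = 0.437 with an estimated correlation). Of 34 proteasome genes, 25 rose and 0 fell (26 adjusted over the list alone), such as PUP3 (0.88 ± 0.06), with a camera adjusted p = 2.98e-05 and an adjusted p = 0.502 with an estimated correlation. Respiration genes fell in 29 of 49 and rose in 6 (29 and 7 adjusted over the list alone), with NDE1 at -1.49 ± 0.12 (camera adjusted p = 0.000193, and adjusted p = 0.437 with an estimated correlation). Drug resistance genes of Pdr1 and Pdr3 fell in 8 of 17 and rose in 3 (8 and 3 adjusted over the list alone), with GRE2 at -1.89 ± 0.17 and RTA1 at 1.31 ± 0.17 (camera adjusted p = 0.00852, and adjusted p = 0.437 with an estimated correlation). Of 9 histone genes, 6 fell (6 adjusted over the list alone), with HTB2 at -0.64 ± 0.08 (camera adjusted p = 0.00450, and adjusted p = 0.437 with an estimated correlation). Seripauperin genes rose in 6 of 13 (6 adjusted over the list alone), with PAU2 at 2.48 ± 0.19 (camera adjusted p = 0.00923, and adjusted p = 0.437 with an estimated correlation). Their call was lost without the 3 YPD arrays numbered 3 (adjusted p = 0.130). Galactose genes rose in 4 of 8 (4 adjusted over the list alone), with GAL7 at 1.27 ± 0.17 (camera adjusted p = 0.0392, and adjusted p = 0.489 with an estimated correlation). The galactose list lost its call without wild type YPD replicate 3 (adjusted p = 0.0782), without the 3 YPD arrays numbered 3 (0.0859) and without BY4742 (0.0808).

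No ribosomal protein gene differed by 2-fold in gal11Δ med3Δ in YPD. Of all 5449 genes 1499 rose and 1056 fell at any size. The shares of cytosolic ones that fell and of mitochondrial ones that rose lay near these. Cytosolic ones fell in 24 of 128 and rose in 1 (13 and 1 adjusted over the list alone), with RPS28B at -0.74 ± 0.06 (camera adjusted p = 1.03e-05, and adjusted p = 0.644 with an estimated correlation). Mitochondrial ones rose in 11 of 43 and fell in 1 (8 and 1 adjusted over the list alone), with MRPL28 at 0.55 ± 0.09 (camera adjusted p = 0.0396, and adjusted p = 0.688 with an estimated correlation). The mitochondrial list lost its call without gal11Δ med3Δ YPD replicate 1 (adjusted p = 0.0885) or 2 (0.0852), without wild type YPD replicate 1 (0.259) or 2 (0.0582) and without BY4742 (0.0538).

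In this comparison limma called 407 of 5449 genes, 254 higher and 153 lower, and 2555 genes had an adjusted p under 0.05 at any size (1499 higher, 1056 lower). The arrays of the 2 groups did not overlap in 52.4% of all genes, where chance gives 10%. Camera called 18 of 30 lists, and with an estimated correlation 3 of them, the a-specific (adjusted p = 0.0153), α-specific (adjusted p = 0.0153) and marker (adjusted p = 0.0431) lists. The strain compared differs from the wild type in mating type as well as in the tail, and these arrays hold no MATα wild type on the same scale. The 12 lists not called were the pheromone, Mediator, Gcn4, purine, phosphate, iron, zinc, glycolysis, hexose transporter, ergosterol, thiamine and COS genes. The pheromone response genes had a median of -0.07 and a mean of 0.11 (3 of 21 rose and 2 fell, camera adjusted p = 0.756).

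Loss of Gal11 and Med3 in CSM asked the same of synthetic medium. MFA2 (-7.87 ± 0.13) and MF(ALPHA)1 (7.17 ± 0.15) differed most. All 7 a-specific genes fell (STE2 -5.43 ± 0.21) and all 5 α-specific genes rose (MF(ALPHA)2 6.74 ± 0.21). ADH2 rose by 5.72 ± 0.36, CDA1 by 4.86 ± 0.19, SNO1, a vitamin B6 gene, by 4.74 ± 0.12, and FRM2 and SRL4 by 4.82 ± 0.15 and 4.55 ± 0.18. YGR109W-A rose by 4.42 ± 0.40. HSP26, a small heat shock protein gene, fell by -5.23 ± 0.38, STP4, a zinc finger protein gene, by -4.35 ± 0.19, and YRO2 by -4.11 ± 0.31. Genes that respond to pheromone rose in 13 of 21 and fell in 0 (14 rose adjusted over the list alone), led by the cell fusion gene FUS1 (3.66 ± 0.15) and PRM2 (3.18 ± 0.35). Their camera adjusted p was 0.00176, and the adjusted p = 0.433 with an estimated correlation. Between the wild types in YPD, whose mating type genes differ, the authors' deposited table gives this list a median of 0.53, with 8 of 21 at least 2-fold positive and 0 negative.

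Of 25 nitrogen catabolite repressed genes in gal11Δ med3Δ in CSM, 23 rose and 0 fell (23 adjusted over the list alone), with GDH2 (2.68 ± 0.23) and the urea transporter gene DUR3 (2.47 ± 0.08) highest (camera adjusted p = 1.58e-08, and adjusted p = 0.0606 with an estimated correlation). Of 30 glucose-repressed genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone), including POX1 (3.69 ± 0.25), SPS19 (3.36 ± 0.14) and CRC1 (3.02 ± 0.17), the carnitine carrier. Camera gave that list an adjusted p = 1.12e-05, and an adjusted p = 0.168 with an estimated correlation. Of 24 sulfur genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with JLP1 (2.67 ± 0.20) and MET2 (2.63 ± 0.37) highest (camera adjusted p = 0.000827, and adjusted p = 0.464 with an estimated correlation). Thiamine genes rose in 11 of 15 and fell in 1 (12 and 1 adjusted over the list alone), with the transporter gene THI7 at 2.36 ± 0.20 (camera adjusted p = 0.00140, and adjusted p = 0.385 with an estimated correlation). Of 47 amino acid biosynthesis genes of the Gcn4 regulon, 23 rose and 9 fell (23 and 9 adjusted over the list alone), with SNZ1 at 2.96 ± 0.15 and ARG3 at -2.17 ± 0.38 (camera adjusted p = 0.00800, and adjusted p = 0.385 with an estimated correlation). Zinc genes rose in 4 of 13, including the transporter gene ZRT1 (3.20 ± 0.17), with the same 4 adjusted over the list alone. That share lay near the share of all genes, of which 1477 of 5449 rose. The zinc list's camera adjusted p was 0.0199, the adjusted p = 0.419 with an estimated correlation, and the call was lost without gal11Δ med3Δ CSM replicate 1 (adjusted p = 0.0688). Subtelomeric seripauperin genes rose in 12 of 13 (12 adjusted over the list alone), with PAU2 at 1.96 ± 0.19 (camera adjusted p = 0.000165, and adjusted p = 0.146 with an estimated correlation).

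Of 36 general stress genes in gal11Δ med3Δ in CSM, 24 fell and 0 rose (24 adjusted over the list alone), among them HSP12 (-3.80 ± 0.69) and YGP1 (-3.68 ± 0.39), with a camera adjusted p = 6.60e-07 and an adjusted p = 0.449 with an estimated correlation. Heat shock and chaperone genes fell in 16 of 30 and rose in 1 (16 and 1 adjusted over the list alone), with HSP30 at -3.75 ± 0.29 (camera adjusted p = 0.00143, and adjusted p = 0.449 with an estimated correlation). Of 35 cell wall genes, 23 fell and 8 rose (23 and 10 adjusted over the list alone), with CWP1 (-2.87 ± 0.19) and the glucanase gene DSE4 (-2.52 ± 0.36) lowest (camera adjusted p = 0.000154, and adjusted p = 0.168 with an estimated correlation). Glycolysis and fermentation genes fell in 9 of 22 and rose in 1 (9 and 1 adjusted over the list alone), with the glycerol biosynthesis genes GPD1 (-1.54 ± 0.17) and GPP2 (-1.16 ± 0.16) lowest (camera adjusted p = 0.00176, and adjusted p = 0.433 with an estimated correlation). Cytosolic ribosomal protein genes fell in 12 of 128 and rose in 2 (7 and 1 adjusted over the list alone), and RPS9A rose by 3.16 ± 0.18. Of all 5449 genes 1004 fell and 1477 rose, so both shares of this list lay below those of all genes. That list's camera adjusted p was 0.0363, the adjusted p = 0.791 with an estimated correlation, and without gal11Δ med3Δ CSM replicate 1 its direction turned (adjusted p = 0.0805). Mitochondrial ribosomal protein genes fell in 13 of 43 and rose in 3 (13 and 3 adjusted over the list alone), with MRPL27 at -1.03 ± 0.07 (camera adjusted p = 0.00425, and adjusted p = 0.575 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 50 and rose in 3 (5 and 3 adjusted over the list alone), with UTP20 at -1.56 ± 0.12 (camera adjusted p = 0.0199, and adjusted p = 0.703 with an estimated correlation). The share of them that fell lay near that of all genes (1004 of 5449). Histone genes fell in 4 of 9 and rose in 2 (5 and 2 adjusted over the list alone), with HTB2 at -0.90 ± 0.08 (camera adjusted p = 0.0359, and adjusted p = 0.476 with an estimated correlation). Ergosterol genes rose in 17 of 29 and fell in 3 (17 and 4 adjusted over the list alone), with ERG26 at 0.67 ± 0.07 (camera adjusted p = 0.0208, and adjusted p = 0.464 with an estimated correlation). Of 9 COS genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with COS12 at 4.12 ± 0.29 and COS111 at -1.27 ± 0.30 (camera adjusted p = 0.0208, and adjusted p = 0.449 with an estimated correlation). The COS call was lost without the 3 YPD arrays numbered 3 (adjusted p = 0.0554), which change only the estimate of the spread here.

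In CSM limma called 506 genes in gal11Δ med3Δ, 276 higher and 230 lower, and 2481 at an adjusted p under 0.05 at any size (1477 higher, 1004 lower). The groups did not overlap in 58.2% of all genes, where chance gives 10%. Camera called 21 of 30 lists, of which the a-specific (adjusted p = 0.0256) and α-specific (adjusted p = 0.0188) lists held with an estimated correlation. Replicate 1 of gal11Δ med3Δ in CSM correlated with its replicates at 0.668 and 0.688 across genes, against 0.963 between the other arrays of the group, and without it the ribosome biogenesis (adjusted p = 0.0805) and histone (adjusted p = 0.103) lists also lost their calls. Ribosome biogenesis genes lost theirs without wild type CSM replicate 3 too (adjusted p = 0.0566). The 9 lists not called were the Mediator, purine, phosphate, iron, drug resistance, hexose transporter, galactose, respiration and proteasome genes. Among iron genes 9 of 25 rose and 6 fell, with a median of 0.36 and a camera test that pointed down (adjusted p = 0.935).

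The gal11-myc med3Δ strain in YPD was compared with the wild type to ask what changes without Med3 when a tagged Gal11 is present. This strain also differs from the wild type in URA3, in LEU2 on a plasmid and in the tag. No change in either medium can therefore be assigned to the loss of Med3 alone. Apart from the markers, COS12 (3.26 ± 0.29), CDA1 (2.78 ± 0.19) and ADH2 (2.73 ± 0.36) rose, as did YGL262W (2.88 ± 0.28) and BNA2 (2.41 ± 0.26), which acts in NAD biosynthesis. The acid phosphatase gene PHO11 (2.35 ± 0.43), MET2 (2.30 ± 0.37) and HUG1 (2.12 ± 0.16), a gene of the DNA damage response, rose too. FMP48 (-3.83 ± 0.19), STP4 (-3.61 ± 0.19), YRO2 (-3.40 ± 0.31) and HSP30 (-3.27 ± 0.29) fell, with RGS2 (-3.08 ± 0.22), a G protein regulator gene, and WSC4 (-3.01 ± 0.23), a cell wall sensor gene. FBP1 fell by -2.82 ± 0.76, but lost its call without gal11-myc med3Δ YPD replicate 3 (-2.05 ± 0.76, adjusted p = 0.0538). It also lost it without the 3 YPD arrays numbered 3 (-2.21, adjusted p = 0.0701) and in a fit of only the 2 groups compared (-2.82 ± 0.86, adjusted p = 0.0680). The a-specific genes rose in 2 of 7 and fell in 1 (2 and 1 adjusted over the list alone), and the α-specific genes rose in 1 of 5 and fell in 1 (1 and 1 adjusted over the list alone), with ASG7 (1.92 ± 0.20) the largest. Neither list was called (camera adjusted p = 0.901 and 0.625).

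Of 24 sulfur genes, 17 rose and 0 fell in gal11-myc med3Δ in YPD (18 adjusted over the list alone), with MET28 (1.96 ± 0.33), a regulator of the pathway, and MET32 (1.89 ± 0.28) among the highest (camera adjusted p = 1.03e-05, and adjusted p = 0.640 with an estimated correlation). Of 35 cell wall genes, 20 fell and 2 rose (21 and 2 adjusted over the list alone), with DSE2 at -1.90 ± 0.16 and SCW11 at -1.69 ± 0.20 (camera adjusted p = 1.03e-05, and adjusted p = 0.471 with an estimated correlation). Nitrogen catabolite repressed genes rose in 12 of 25 and fell in 1 (13 and 1 adjusted over the list alone), with GAP1 at 1.69 ± 0.18 (camera adjusted p = 0.00485, and adjusted p = 0.640 with an estimated correlation). Gcn4 regulon genes rose in 19 of 47 and fell in 3 (24 and 5 adjusted over the list alone), with SNO1 at 1.81 ± 0.12 and ARG4 at 1.15 ± 0.16 (camera adjusted p = 0.00485, and adjusted p = 0.640 with an estimated correlation). Drug resistance genes of Pdr1 and Pdr3 fell in 9 of 17 and rose in 4 (9 and 4 adjusted over the list alone), with the transporter gene SNQ2 at -1.46 ± 0.13 (camera adjusted p = 0.00485, and adjusted p = 0.640 with an estimated correlation). Ribosome biogenesis genes fell in 7 of 50 (1 adjusted over the list alone), with UTP20 at -0.51 ± 0.12 (camera adjusted p = 0.000454, and adjusted p = 0.786 with an estimated correlation). The share of them that fell lay near that of all genes (659 of 5449). Histone genes fell in 5 of 9 (5 adjusted over the list alone), with HTB2 at -0.51 ± 0.08 (camera adjusted p = 0.00351, and adjusted p = 0.640 with an estimated correlation). COS genes rose in 5 of 9 (6 adjusted over the list alone), led by COS12 at 3.26 ± 0.29 (camera adjusted p = 0.0141, and adjusted p = 0.713 with an estimated correlation). Glycolysis and fermentation genes fell in 5 of 22 and rose in 2 (5 and 2 adjusted over the list alone), with GPD1 at -2.10 ± 0.17 (camera adjusted p = 0.0119, and adjusted p = 0.713 with an estimated correlation). They lost the call without gal11-myc med3Δ YPD replicate 1 (adjusted p = 0.0515) and wild type YPD replicate 3 (adjusted p = 0.0696). Cytosolic ribosomal protein genes rose in 1 of 128 and fell in 1 (0 and 0 adjusted over the list alone), with RPL15B at 0.39 ± 0.10 (camera adjusted p = 0.00485, and adjusted p = 0.807 with an estimated correlation). These counts and that single gene give the call no direction. The hexose transporter gene HXT1 fell by -2.50 ± 0.39, while its list, with 4 of 15 up and 5 down (4 and 5 adjusted over the list alone), was not called (camera adjusted p = 0.336). In total, limma called 236 genes, 140 higher and 96 lower, and 1816 at an adjusted p under 0.05 at any size (1157 higher, 659 lower). Camera called 10 of 30 lists, none of which held with an estimated correlation. Groups did not overlap in 42.0% of all genes, where chance gives 10%. Heat shock genes, with a median of 0.14 and a mean of -0.04, were among the 20 lists not called (camera adjusted p = 0.492). The authors' deposited table, with its own filter and test, holds 102 genes at 2-fold or more and a corrected p under 0.05 for this comparison, 101 of them called here.

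In CSM the gal11-myc med3Δ strain had higher ADH2 (4.30 ± 0.36), CDA1 (3.89 ± 0.19), ANB1 (3.73 ± 0.17), a gene of low oxygen growth, COS12 (3.59 ± 0.29) and BNA2 (3.24 ± 0.26). RPS9A (3.01 ± 0.18), MET2 (3.01 ± 0.37) and THI7 (2.95 ± 0.20) also rose. ECM13 (-4.62 ± 0.31), HSP26 (-3.80 ± 0.38) and PHM8 (-3.50 ± 0.39) fell, together with ARO10 (-3.47 ± 0.38) and ARO9 (-2.80 ± 0.26), which break down aromatic amino acids, STP4 (-3.15 ± 0.19), FMP48 (-2.92 ± 0.19), MGA1 (-2.79 ± 0.30) and PRY3 (-2.67 ± 0.25). As in YPD, the a-specific list (2 of 7 rose, 1 fell) and the α-specific list (2 of 5 rose) were not called (camera adjusted p = 0.456 and 0.0892), with the same counts adjusted over the list alone.

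General stress genes fell in 17 of 36 and rose in 1 in gal11-myc med3Δ in CSM (20 and 1 adjusted over the list alone), with the trehalose synthesis gene TSL1 at -1.53 ± 0.38 and DDR2 at -1.48 ± 0.40 (camera adjusted p = 3.01e-05, and adjusted p = 0.635 with an estimated correlation). Cell wall genes fell in 19 of 35 and rose in 6 (19 and 6 adjusted over the list alone), with SCW11 (-2.46 ± 0.20), DSE4 (-2.40 ± 0.36), DSE2 (-2.37 ± 0.16) and EGT2 (-2.04 ± 0.37) lowest. Wall genes as a list had a camera adjusted p = 0.00101, and an adjusted p = 0.585 with an estimated correlation. Sulfur genes rose in 15 of 24 and fell in 1 (16 and 1 adjusted over the list alone), with MMP1 at 2.56 ± 0.40 (camera adjusted p = 0.00291, and adjusted p = 0.635 with an estimated correlation). Thiamine genes rose in 9 of 15 and fell in 2 (9 and 2 adjusted over the list alone), with THI13 at 1.99 ± 0.10 (camera adjusted p = 0.00751, and adjusted p = 0.585 with an estimated correlation). Zinc genes rose in 7 of 13 (7 adjusted over the list alone), with ZRT1 at 2.76 ± 0.17 (camera adjusted p = 0.0182, and adjusted p = 0.585 with an estimated correlation). Ergosterol genes rose in 14 of 29 and fell in 1 (15 and 1 adjusted over the list alone), with ERG26 at 0.70 ± 0.07 (camera adjusted p = 0.00547, and adjusted p = 0.585 with an estimated correlation). Glycolysis and fermentation genes fell in 8 of 22 and rose in 1 (8 and 1 adjusted over the list alone), with GPD1 at -1.25 ± 0.17 (camera adjusted p = 0.00291, and adjusted p = 0.585 with an estimated correlation). Glucose-repressed genes rose in 10 of 30 and fell in 1 (10 and 1 adjusted over the list alone), with SPS19 at 2.50 ± 0.14 and CRC1 at 2.17 ± 0.17 (camera adjusted p = 0.0177, and adjusted p = 0.635 with an estimated correlation). COS genes rose in 7 of 9 and fell in 1 (7 and 1 adjusted over the list alone), with COS8 at 0.99 ± 0.13 (camera adjusted p = 0.0104, and adjusted p = 0.585 with an estimated correlation). Seripauperin genes rose in 6 of 13 (6 adjusted over the list alone), with PAU2 at 1.69 ± 0.19 (camera adjusted p = 0.0177, and adjusted p = 0.585 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 10 of 43 and rose in 1 (9 and 1 adjusted over the list alone), with MRPL27 at -1.02 ± 0.07 (camera adjusted p = 0.0124, and adjusted p = 0.777 with an estimated correlation).

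In the same comparison 2 called lists lay close to the threshold of 0.05. Ribosome biogenesis genes rose in 14 of 50 and fell in 2 (14 and 2 adjusted over the list alone), with NOP1 at 0.68 ± 0.13 (camera adjusted p = 0.0472, and adjusted p = 0.783 with an estimated correlation). The share of them that rose lay only a little above that of all genes (1223 of 5449). Histone genes fell in 5 of 9 and rose in 2 (5 and 2 adjusted over the list alone), with HTB2 at -0.65 ± 0.08 (camera adjusted p = 0.0481, and adjusted p = 0.635 with an estimated correlation). The ribosome biogenesis list lost its call without gal11-myc med3Δ CSM replicate 2 (adjusted p = 0.101) or 3 (0.0631) and without wild type CSM replicate 1 (0.119) or 2 (0.0581). The histone list lost it without gal11-myc med3Δ CSM replicate 3 (adjusted p = 0.0607) and without wild type CSM replicate 1 (0.0535) or 2 (0.0581). It was also lost without BY4742 (0.0642), without the 3 YPD arrays numbered 3 (0.0572) and with each array centred on its gene median (0.0569). Nitrogen catabolite repressed genes rose in 8 of 25 and fell in 3 (8 and 3 adjusted over the list alone), and that list was not called (camera adjusted p = 0.516). Limma called 339 genes, 161 higher and 178 lower, and 1995 at an adjusted p under 0.05 at any size (1223 higher, 772 lower). Camera called 13 of 30 lists, none of which held with an estimated correlation. Groups did not overlap in 70.7% of all genes, where chance gives 10%. Heat shock genes, with a median of 0.01 and a mean of -0.35, were among the 17 lists not called (5 of 30 rose and 7 fell, camera adjusted p = 0.188).

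**Figure D2:**
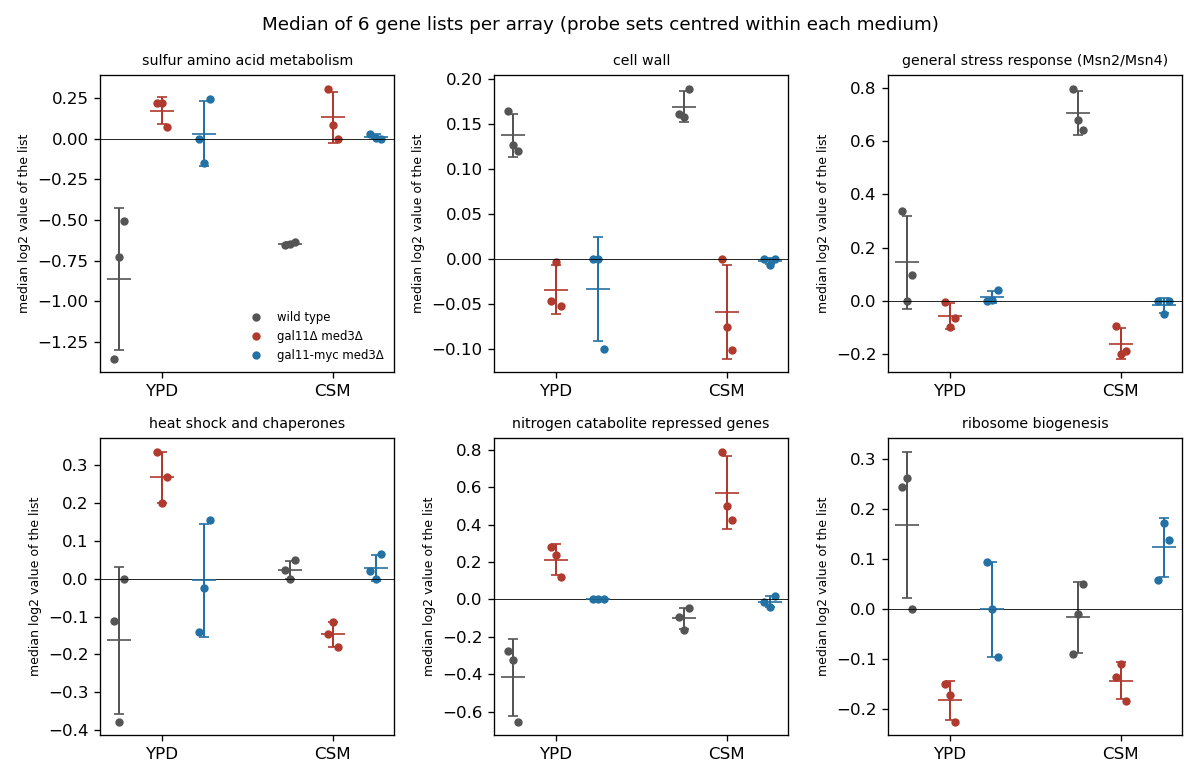
Median log2 value of 6 gene lists on each array (y axis), where each probe set was centred within its medium by the authors, so that heights compare strains within a medium and not between media. Points are arrays, dashes are means of 3 arrays and bars are SD. The wild type mean lies lowest for sulfur genes and highest for cell wall genes in both media, and highest for general stress genes in CSM.

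The mutants were then compared with each other. They differ in Gal11, but also in mating type and in LYS2, URA3 and LEU2, so no difference below can be assigned to Gal11 alone. In YPD limma called 110 genes, 42 higher and 68 lower in gal11-myc med3Δ than in gal11Δ med3Δ, and in CSM 118, with 38 higher and 80 lower. The YPD count depended on single arrays, with 80 higher and 85 lower without gal11-myc med3Δ YPD replicate 3, and 24 and 69 without gal11Δ med3Δ YPD replicate 3. The groups did not overlap in 31.0% of all genes in YPD and 41.5% in CSM, where chance gives 10%. At any size, 823 and 976 genes had an adjusted p under 0.05. The largest were again the markers and mating type genes, such as GAL11 (5.84 ± 0.15 in YPD, 5.07 ± 0.15 in CSM), MFA2 (6.98 ± 0.13, 7.29 ± 0.13), LYS2 (6.76 ± 0.13, 5.96 ± 0.13) and MF(ALPHA)1 (-7.68 ± 0.15, -7.00 ± 0.15). Nitrogen catabolite repressed genes were lower in gal11-myc med3Δ in CSM in 16 of 25 and higher in 0 (19 lower adjusted over the list alone), and this list held with an estimated correlation (adjusted p = 0.00652). In YPD it was lower in 9 and higher in 1 (11 and 1 adjusted over the list alone), with a camera adjusted p = 0.00175 and an adjusted p = 0.400 with an estimated correlation. In CSM, glucose-repressed genes were lower in 12 of 30 (13 adjusted over the list alone, camera adjusted p = 9.91e-08, and adjusted p = 0.103 with an estimated correlation). Gcn4 regulon genes were lower in 17 of 47 and higher in 1 (17 and 2 adjusted over the list alone, camera adjusted p = 2.90e-05, and adjusted p = 0.103 with an estimated correlation). Ribosome biogenesis genes were higher in 23 of 50 (31 adjusted over the list alone, camera adjusted p = 3.24e-11, and adjusted p = 0.281 with an estimated correlation). Cell wall genes were not called in either medium (camera adjusted p = 0.707 in YPD and 0.109 in CSM), nor were sulfur genes (0.395 and 0.110). Camera called 14 lists in YPD and 12 in CSM, of which 3 and 4 held with an estimated correlation: the marker, a-specific and α-specific lists in both media, and the nitrogen list in CSM. Lists between the mutants were not retested with single arrays left out, among them the outlying gal11Δ med3Δ CSM replicate 1. With the replicate block 11 of the 12 lists in CSM kept their call, and the galactose genes did not (adjusted p = 0.0552).

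Both mutants were set side by side to ask how many genes they share. In YPD, 100 genes were called higher and 84 lower in both, 184 in all, against 6.53 and 2.70 if the calls were independent. In YPD 1 gene was called in opposite directions. In CSM, 139 were higher and 134 lower in both, 273 in all, against 8.15 and 7.51, with 1 opposite. Both mutants share their wild type arrays within a medium, so part of the excess may come from those arrays. In 100 simulated sets of unchanged arrays the shared arrays alone gave a correlation of 0.496 between the 2 mutants' differences in YPD and 0.499 in CSM. The measured correlations were 0.723 and 0.767. The measured covariances were 0.233 and 0.297, against a simulated 0.0105 in each medium. The simulated arrays were independent, so these values leave out the pairing of the YPD arrays by replicate number. Across media, where no array is shared, 145 genes were shared by gal11Δ med3Δ in YPD and gal11-myc med3Δ in CSM, and 146 by the reverse pair, with 9 and 2 called in opposite directions. Within a strain, gal11Δ med3Δ shared 199 genes between the media and gal11-myc med3Δ 136, with 9 and 1 opposite. STP4, YRO2 and COS12 are among the genes named in both strains, and the plot of 12 named genes shows their values on each array.

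**Figure D3:**
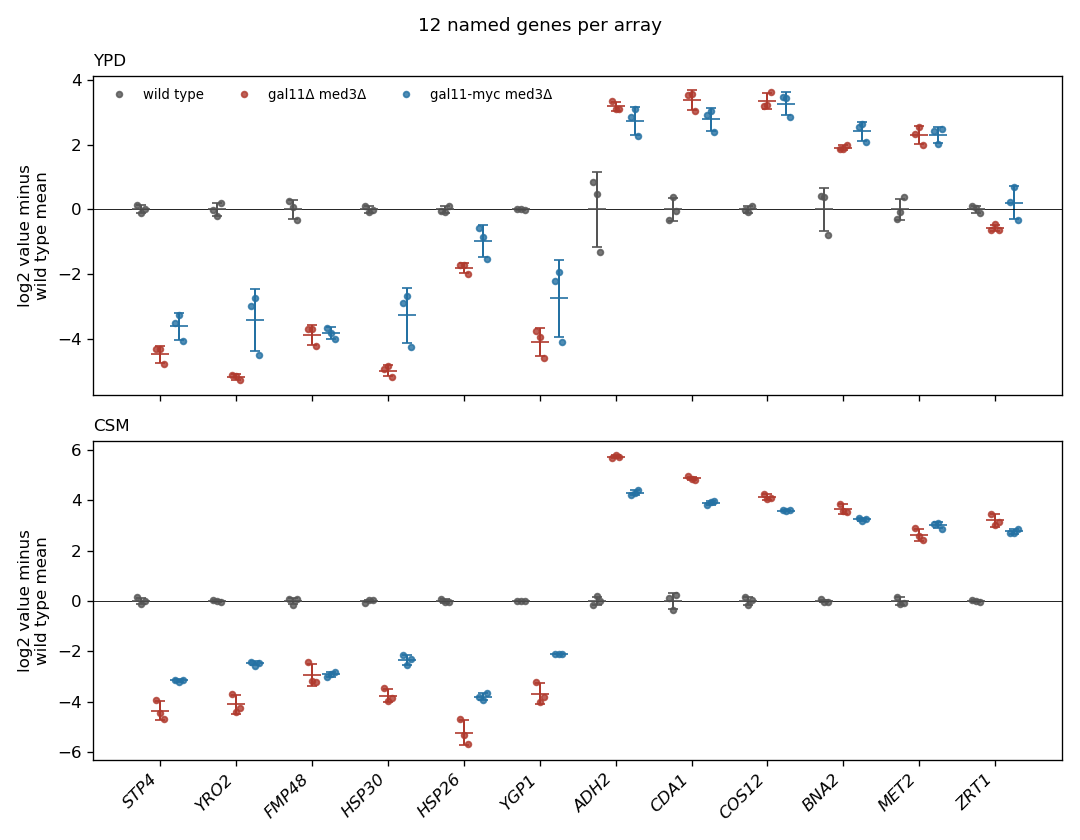
Log2 values of 12 named genes on each array, minus the mean of the 3 wild type arrays in the same medium (y axis, log2). Points are arrays, dashes are means of 3 arrays and bars are SD. STP4, YRO2, FMP48 and HSP30 lie below the wild type and ADH2, CDA1, COS12, BNA2 and MET2 above it in both mutants and both media, while ZRT1 lies high in CSM only.

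The dependence of each mutant's effect on medium was tested as an interaction, CSM effect minus YPD effect. For gal11Δ med3Δ, limma called 391 genes (176 higher, 215 lower) and for gal11-myc med3Δ 167 (54 higher, 113 lower). The nutrient transporter genes PHO84 (phosphate, 4.91 ± 0.55) and ZRT1 (zinc, 3.77 ± 0.25) had more positive effects in CSM in gal11Δ med3Δ, as did FBP1 (5.03 ± 1.08) and CHA1 (4.67 ± 0.45), while HSP26 (-3.43 ± 0.54) and MIG3 (-2.93 ± 0.50) had more negative ones. In gal11-myc med3Δ, ZRT1 (2.55 ± 0.25), the hexose transporter gene HXT2 (2.77 ± 0.28) and RPS9A (2.71 ± 0.25) were more positive in CSM, and ECM13 (-2.99 ± 0.43), HSP26 (-2.81 ± 0.54) and HIS4 (-2.61 ± 0.38) more negative. Of 30 heat shock and chaperone genes, 22 had a more negative effect in CSM and 1 a more positive one in gal11Δ med3Δ (23 and 1 adjusted over the list alone), with a camera adjusted p = 1.23e-08 and an adjusted p = 0.698 with an estimated correlation. Thiamine genes were more positive in CSM in 11 of 15 and more negative in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000433, and adjusted p = 0.698 with an estimated correlation). Proteasome genes were more negative in 15 of 34 (16 adjusted over the list alone, camera adjusted p = 3.19e-05, and adjusted p = 0.713 with an estimated correlation). Camera called 13 and 11 of 30 lists in the 2 interactions, none with an estimated correlation. With the replicate block 12 of the 13 kept their call, and the iron genes did not (adjusted p = 0.0571).

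The authors' deposited table also compares the wild types in YPD, which the centred values do not allow. Its positive direction was taken here as BY4742 over BY4741, since LYS2, which the BY4742 label lists as deleted, stands at -6.47 and MET17, deleted in BY4741, at 8.78 (log2). There, 17 genes had a corrected p under 0.05. Of the listed mating type genes, 12 of the 12 differed by at least 2-fold with the α-specific genes positive (MF(ALPHA)1 8.90, MFA2 -7.35). In all, 99 genes were at least 2-fold positive and 27 negative. Of the 407 genes called in gal11Δ med3Δ in YPD, 51 differed there by at least 2-fold in the same direction and 10 in the opposite one. Of the 407, 15 also had a corrected p under 0.05 there. Both comparisons are against the wild type in YPD, so part of any agreement, here and in the list medians below, may come from shared wild type arrays. The list medians there were 0.97 for sulfur genes, 0.69 for general stress genes, 0.53 for pheromone response genes, 0.30 for heat shock genes, -0.33 for ribosome biogenesis genes and -0.04 for cell wall genes. The ribosome biogenesis median in gal11Δ med3Δ in YPD was -0.38. BY4742 replicate 1 stood apart from its replicates, with general stress genes at a median of -1.10 against 0.00 and 0.17 on the other 2, so these medians rest on unlike arrays. The BY4742 label gives MATa. In the authors' deposited table, however, its α-specific genes stood above and its a-specific genes below those of BY4741, so label and expression disagree.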

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

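The tests of the mating type genes, the sulfur genes, the wild type state and the splits were chosen after the results were seen, as were the tests of the added meiosis list. The tests of single arrays for the heat shock genes were written before their results.

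The difference between gal11Δ med3Δ and the wild type changed with the medium for 391 genes and 13 lists, tested as an interaction. That strain also differs in mating type and LYS2, so an interaction cannot be assigned to Gal11 and Med3 alone. No list held with an estimated correlation (lowest adjusted p = 0.698). The largest were YGR109W-A (5.16), FBP1 (5.03), PHO84 (4.91), CHA1 (4.67) and ZRT1 (3.77), which were more positive in CSM, and SPO22 (-3.43), HSP26 (-3.43), MIG3 (-2.93), COS111 (-2.58) and DLD3 (-2.55), which were more negative. Among strain marker and mating type genes the interaction was 0.81 for GAL11, 2.34 for MFA1, 0.76 for STE6, 1.44 for MF(ALPHA)2, 1.67 for SAG1 and 0.73 for AFB1. GAL11 is deleted in this strain and the mating type genes are silent in 1 of the 2 mating types, so these values depend on signal at background, which centring hides, and are not read as effects of the medium. In gal11-myc med3Δ, 167 genes and 11 lists differed between the media, and again no list held with an estimated correlation (lowest adjusted p = 0.678). That strain also differs in URA3, LEU2 and the tag, so its interaction cannot be assigned to Med3 alone. HXT2 (2.77), RPS9A (2.71), ZRT1 (2.55), CRC1 (2.46) and SHH3 (2.28) were more positive in CSM, and ECM13 (-2.99), HSP26 (-2.81), HIS4 (-2.61), SPO22 (-2.30) and GAL7 (-2.23) more negative. Among markers and mating type genes the interaction was -0.39 for HIS3, -0.94 for URA3, -1.18 for LYS2 and 1.22 for AFB1, where the same caution holds for the deleted or silent genes.

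Probe sets with no gene name lie outside the gene comparisons. Of these, 20 in YPD and 21 in CSM were called in gal11Δ med3Δ, and 13 and 11 in gal11-myc med3Δ. A reporter probe set stood 10.83 above the wild type in gal11Δ med3Δ in YPD and 9.63 in CSM. Another stood 3.62 above it in gal11-myc med3Δ in YPD and 1.62 in CSM. Control probe sets for URA3, a marker of gal11-myc med3Δ, stood up to 7.52 above it there in YPD and 6.12 in CSM. Among probe sets that are neither controls nor reporters, the largest rises were 2.28 and 5.70 in gal11Δ med3Δ, and 1.76 and 2.08 in gal11-myc med3Δ. The largest falls were in a single probe set, by -2.94 and -3.38 in gal11Δ med3Δ, and -2.87 and -2.86 in gal11-myc med3Δ.

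The mating type genes of gal11Δ med3Δ followed the strain's label. Of the 12 genes, 12 differed by at least 2-fold in the same direction between the wild types with an intact tail in the authors' deposited table. Loss of Med3 alone was argued against, since the lower of the medians of the a-specific genes in gal11-myc med3Δ was -0.0815. The mating type of the strain may account for these genes, and a part played by Gal11 could not be separated from it.

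The sulfur amino acid genes were higher in both mutants and both media, but as a list lost the call in all 4 comparisons with an estimated correlation (adjusted p = 0.437, 0.464, 0.640 and 0.635). A different MET17 genotype was argued against by the largest MET17 difference of 0.17, and a single array by the highest adjusted p of 0.00394 with any 1 array left out. In the authors' deposited table the same genes had a median of 0.97 between the wild types, so wild type YPD arrays that lie low whatever the tail may account for the YPD part. Those wild types differ in MET17, however, so their difference and the state of the BY4741 cultures remain confounded. No such comparison exists in CSM, and a role of the tail remains open there.

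The median of the heat shock and chaperone genes lay on opposite sides of the wild type in the 2 media in gal11Δ med3Δ, with a median interaction of -0.73. Not all members did so, since HSP30, HSP12 and HSP26 fell in both media. Without the 3 YPD arrays numbered 3 the camera p was 1.99e-10, and without gal11Δ med3Δ CSM replicate 1 it was 1.96e-08, so neither accounts for the pattern alone. With an estimated correlation the p was 0.0336 for this list alone, 0.0346 and 0.0715 in those 2 fits, and the adjusted p over the lists was 0.698. The median between the wild types in the authors' deposited table was 0.30, so the state of the wild type cultures in YPD may account for part of the YPD side.

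The arrays of 2 groups can be split in 10 ways, too few to judge the count of genes called by chance, and 1 split, the real one, gave as many genes in each of the 6 comparisons. The real counts and the highest of the other splits were 407 and 2 for gal11Δ med3Δ in YPD, 506 and 0 in CSM, 236 and 15 for gal11-myc med3Δ in YPD, 339 and 0 in CSM, 110 and 0 between the mutants in YPD, and 118 and 0 in CSM. For the interactions, 1 of 100 splits of the medium labels within each genotype gave as many genes as the 391 of gal11Δ med3Δ (highest other 200), and 3 of 100 as many as the 167 of gal11-myc med3Δ (highest other 186). That scheme replaced splits of the genotype labels within each medium, after their result had been seen, which were also 1 of 100 (highest other 360) and 3 of 100 (highest other 253). Under both schemes the share lay below 0.05, but arrays are exchanged freely there. The YPD arrays may not be free to exchange, so chance is not excluded by these shares. Replicate numbers pair at least some of the YPD arrays, so the real split was also set beside those that part all 3 YPD pairs, as it does. In each YPD comparison there were 4 such splits, too few for that share, and the highest of the others called 0 genes. For the medium labels there were 11, again too few, and the highest others were 1 and 0. For the genotype labels 1 of 40 gave as many genes in each mutant (highest other 318 and 158). The other splits that reached the 167 parted fewer pairs.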

How the results depend on the processing

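The block within each medium, the fits without BY4742, without the YPD arrays numbered 3 or without probe sets that can match several genes, and most settings for the overlap were chosen after the results were seen. With the replicate block 408, 506, 237 and 340 genes were called in gal11Δ med3Δ and gal11-myc med3Δ (YPD, then CSM, each), 111 and 118 between the mutants, and 392 and 166 in the interactions, with 184 and 273 shared. Over 9 settings other than the fold these counts ranged over 395 to 449, 487 to 527, 215 to 269, 326 to 353, 94 to 157, 112 to 127, 379 to 468 and 163 to 229. Leaving out 1 array gave 391 to 448, 495 to 517, 239 to 271, 334 to 343, 85 to 165, 108 to 127, 358 to 459 and 152 to 219. At 1.5-fold they were 998, 1068, 620, 817, 328, 299, 948 and 483, and the shared genes 473 in YPD and 647 in CSM. Counts at any size moved more. In a fit of only the groups compared they were 1963 and 2387 in gal11Δ med3Δ (YPD, then CSM), and 1147 and 3492 in gal11-myc med3Δ. Array weights with a robust variance gave 3472 and 4016, and 3537 and 3819, against 2555, 2481, 1816 and 1995 in the main fit. The counts of list members rest on the same threshold and were not recounted. The authors' deposited table held 313 and 473 genes for gal11Δ med3Δ and 102 and 350 for gal11-myc med3Δ (YPD, then CSM), of which 307, 471, 101 and 338 were called here. Shared genes were 173 to 205 in YPD and 269 to 278 in CSM with 1 array left out, and 146 for gal11Δ med3Δ in CSM with gal11-myc med3Δ in YPD. With an estimated correlation 3, 2, 0 and 0 lists were called, and with 1 array left out 15 to 19, 17 to 21, 11 to 15 and 11 to 13. The fry test, which does not compare a list with other genes, called 21, 21, 14 and 19, against 18, 21, 10 and 13 by camera. Of 682 list values 591 were the same, 90 lost the call and 1 turned. That was the cytosolic ribosomal protein list of gal11Δ med3Δ in CSM, whose adjusted p was 0.0805 without replicate 1, and 0.000262 to 0.0805 with 1 array left out. Of 2177 values of 136 named results 17 lost the adjusted p under 0.05, in 5 results, of which only FBP1 had met the 2-fold threshold: HIS3 in gal11Δ med3Δ in YPD, GAL11 and FBP1 in gal11-myc med3Δ in YPD, and HIS3 and URA3 in the interaction of gal11-myc med3Δ. The cause was not tested. A filter on dim probe sets, a second quantile normalization, the probe set with the highest mean, a variance trend, every comparison with BY4742, the wild type between media and the TATA test were not run, since centring or the lack of a genome left no value.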

Other observations

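The list of meiosis genes was chosen after some of its members had been seen among the largest changes.

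Meiosis and sporulation genes rose in 20 of 53 and fell in 6 in gal11Δ med3Δ in YPD, and rose in 23 and fell in 5 in CSM. In gal11-myc med3Δ 19 rose and 4 fell in YPD, and 18 rose and 6 fell in CSM. IME1, the inducer of meiosis, was lower in all 4 comparisons, with -0.74 ± 0.11 and -1.06 ± 0.11 in gal11Δ med3Δ and -0.82 ± 0.11 and -0.44 ± 0.11 in gal11-myc med3Δ. The meiosis-specific gene SPO22 was higher in YPD (1.37 ± 0.20 in gal11Δ med3Δ) and lower in CSM (-2.06 ± 0.20).

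Without the members seen first, the 45 remaining meiosis genes were not called by camera, with an adjusted p of 0.313 in YPD and 0.155 in CSM in gal11Δ med3Δ, and 0.225 and 0.349 in gal11-myc med3Δ. With an estimated correlation the adjusted p was 0.680 in each mutant in CSM, so no shift of the list as a set was shown.

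In YPD, deviations of same-numbered arrays from their group means correlated in all 9 pairs (0.146 to 0.606), and in 7 of them their own number gave the highest value. Replicate 3 of gal11-myc med3Δ in YPD correlated with its replicates across genes at 0.0567 and 0.181, against 0.806 between the other 2. Replicate 3 stood apart in the other YPD strains too, at 0.623 and 0.657 against 0.911 in the wild type. In gal11Δ med3Δ it stood at 0.784 and 0.850 against 0.937. These are correlations of centred values, which hold no differences in level between genes, so a low value does not by itself show a failed array.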
